A study of Mus musculus with 18 samples.

How the data were processed

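RNA sequencing of total RNA (10 ng input) from KP2 mouse organoids gave 18 libraries, 3 for each of 6 treatments lasting 24 h, and all 18 were used. The deposited files hold, per the file headers, estimated counts per gene (NumReads) and TPM with gene lengths and effective lengths for 55487 gene IDs, a layout that salmon writes. The authors made the estimated counts before deposit, per the submitters' processing notes, from reads written by bcl2fastq and aligned with STAR 2.5.1a to mm10. The authors' TPM values matched estimated counts over effective length, rescaled, to within 1.17% for values over 50 counts, and TPM entered only read shares given as an alternative. All 18 read shares moved over 1.5 times as TPM shares, such as ribosomal proteins in vehicle organoids from 6.295% to 13.52%. TPM divides counts by effective length, so a TPM share is a different measure from a share of counts. The notes do not name the program that made the gene values or state the library strand, so reads from an overlapping antisense gene may be included, and near-identical family members share reads. Of the gene IDs, 55141 were matched to symbols of GENCODE vM21 (GRCm38) and 346 were not. IDs without a symbol held at most 0.066% of the counts of any library.

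Estimated counts were rounded to whole numbers, and 71.7% of the nonzero values were whole as deposited. Libraries held 27391852 to 35820741 counts, where a floor of 3 counts corresponds to about 0.1 CPM. Genes were filtered with filterByExpr on the group, which left 16747 genes tested, and libraries were scaled by TMM. All 18 libraries entered a single edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with a coefficient per group, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.097. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with adjusted p under 0.05 are said to have passed, risen, fallen or changed. There were 9 comparisons between groups and 2 interactions on the log2 scale, FAKi by MEKi and gemcitabine by the inhibitor pair. Principal components were taken from log2 CPM (prior count 2) of genes with a mean of at least 1 CPM.

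The 31 gene lists were written before the data were examined, from general knowledge of pathways and cell types, and lists with at least 5 measured members were tested by camera with the preset correlation of 0.01. Their p-values were adjusted by the Benjamini-Hochberg method over the lists of a comparison. The list test was repeated with the correlation estimated from the data. Beside it, fry was run, which tests a list against no change, while camera tests it against the other genes. A call by fry therefore answers another question than a call by camera. Counts of members are given from p-values adjusted over all genes and, beside them, adjusted over the list alone.

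Genes are named by a fixed rule. For each comparison of groups it takes up to 10 largest rises and falls with adjusted p under 0.05, at least 5 CPM in the higher group, no overlap of CPM between the groups and no model-number symbol. It adds up to 4 members of each list with the smallest p and a fixed set of anchor genes, such as drug targets and pathway readouts. For interactions it takes up to 5 genes in each direction with no overlap rule. The text gives a selection of these genes.

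The test was tested on simulated data made from these libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 16747. For FAKi against vehicle it recovered 62.7%, 89.6% and 97.0% of them, with 7.3% of calls false. For the triple combination against the pair it recovered 70.1%, 92.5% and 100.0%, with 4.5% false, and for the gemcitabine interaction 37.3%, 86.6% and 97.0%, with 5.6% false. A simulated list of 50 members raised 1.5-fold had an adjusted p of 6.95e-89 with the preset and 4.68e-09 with the estimated correlation, and 0 of 99 unchanged lists were called. The changed genes were drawn from genes with an average log2 CPM above 0, and unchanged genes kept their vehicle mean in all groups. Fewer genes were changed than passed in the data. The rates therefore need not hold for genes at lower levels or for comparisons in which many genes change. The simulated genes varied independently of each other. For lists whose members vary together, such as mitosis (estimated correlation 0.534 for FAKi against vehicle), the simulation cannot show how often false calls arise.

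The alternatives tried were RLE size factors, an offset for effective length, no count filter, DESeq2 1.42.0, a fit to only the groups of the comparison, a replicate block, and leaving out each library in turn. Their effect is given in the closing section.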

Results

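Gene expression was measured by RNA sequencing of total RNA from organoids of KP2, a mouse pancreatic ductal adenocarcinoma line. The line carries a pancreas-directed Cre driver, an inducible oncogenic Kras allele and floxed Trp53 alleles, per the labels. Organoids, which are epithelial cells grown as 3-dimensional structures, were treated for 24 h and fell into 6 groups of 3 libraries each. The groups were Vehicle, an inhibitor of focal adhesion kinase (FAKi), an inhibitor of the kinase MEK (MEKi), FAKi with MEKi (here the inhibitor pair), gemcitabine, and gemcitabine with FAKi and MEKi (here the triple combination). Focal adhesion kinase (gene Ptk2) carries signals from integrins, MEK (genes Map2k1 and Map2k2) activates the kinase ERK downstream of KRAS, and gemcitabine is a nucleoside analogue that blocks DNA synthesis. The labels do not name the compounds behind FAKi and MEKi or their doses. Each library held between 27391852 and 35820741 estimated counts, and 3 counts, the floor used here, correspond to about 0.1 CPM, the unit used here for counts scaled to a common library total. Intervals and floors of this kind cover counting error only, because the counts are not tied to molecular identifiers. The labels do not say that the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Unless stated otherwise, values are mean CPM ± SD over n = 3 libraries, and changes are log2 fold changes with their standard error (SE).

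The 6 groups separated from each other in a principal component analysis, with 60.7% of the variance on the first component and 13.5% on the second. The genotype genes and drug targets were expressed in every group. Trp53 stood at 8.44 ± 0.358 CPM in vehicle organoids and 7.49 ± 0.640 CPM with gemcitabine, and Kras at 28.9 ± 1.21 and 30.2 ± 0.593 CPM. Values per gene do not separate the floxed exons of Trp53 or the mutant Kras allele from the normal one, so they do not check the genotype. Ptk2 (ENSMUSG00000022607, chromosome 15, 73205102 to 73423280, minus strand, GRCm38/mm10) stood at 77.6 ± 2.38 CPM in vehicle organoids, 69.7 ± 2.53 CPM with FAKi, 38.7 ± 1.08 CPM with MEKi and 105 ± 5.06 CPM with gemcitabine.

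**Figure D1:**
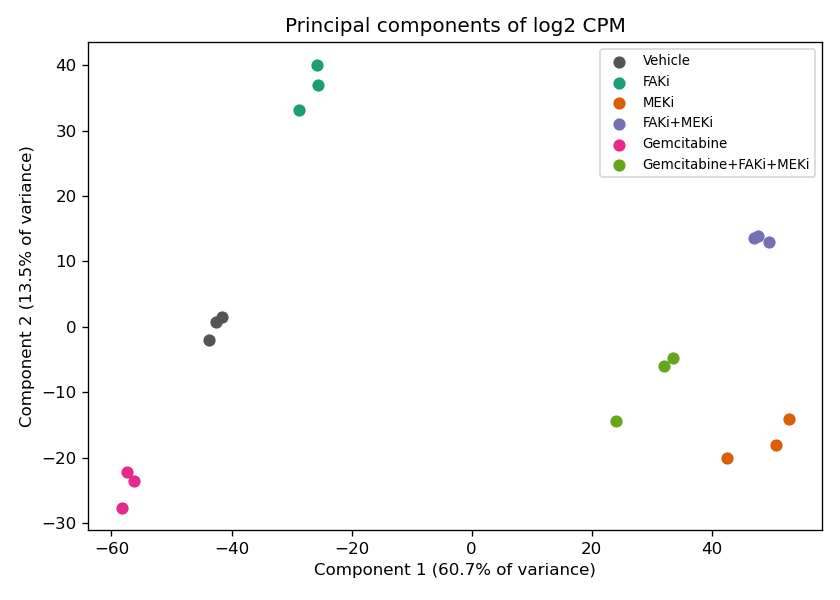
Principal components 1 and 2 (scores, no unit) of log2 CPM for the 18 libraries, with 1 point per library coloured by group. Component 1 carries 60.7% of the variance, and the libraries with MEKi lie on its right side, from 24.04 (triple combination) to 52.81 (MEKi).

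The first comparison asked what FAKi alone did. After 24 h of FAKi, genes of DNA replication and cell division fell together. Mki67, a marker of cycling cells, changed by -2.24 (SE 0.20), from 29.0 ± 2.85 to 6.15 ± 1.29 CPM. The gene for cyclin D1, Ccnd1, which drives entry into the cell cycle, changed by -1.23 (SE 0.09), and the ETS transcription factor gene Etv5 by -1.11 (SE 0.23). In contrast, Dusp6, an ERK phosphatase gene used as a readout of ERK activity, did not pass the test (-0.17, adjusted p = 0.325). Myc (0.06, adjusted p = 0.696) and Ptk2 itself (-0.15, adjusted p = 0.114) did not pass either, although Ptk2 did with an effective-length offset (adjusted p = 0.0284). Among the largest rises were Try5, a trypsin gene (2.70, SE 0.12), Hp, which encodes haptoglobin (2.31, SE 0.21), Gdf15, a stress-induced cytokine gene (2.13, SE 0.17), and Dusp16, which encodes a phosphatase of stress kinases (1.73, SE 0.07). Try5 belongs to a family of near-identical trypsin genes, so its value is uncertain. The largest falls included Ankle1 (-2.85, SE 0.22), Troap (-2.53, SE 0.19), the kinetochore gene Nuf2 (-2.46, SE 0.20) and Pclaf, which encodes a PCNA-binding factor (-2.40, SE 0.19).

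Among the lists, the DNA replication list stood out, as 49 of 51 measured members fell (50 adjusted over the list alone), with a median of -1.18 (camera, adjusted p = 8.25e-77, and adjusted p = 0.000471 with an estimated correlation). Its members Rrm2, a subunit of ribonucleotide reductase (-1.90), and Mcm5, a subunit of the replicative helicase (-1.88), were among those that fell. In the mitosis list, 49 of 50 measured members fell and 1 rose (49 and 1 adjusted over the list alone), including Kif2c (-2.11), Ube2c (-2.19) and Racgap1 (-1.86) (adjusted p = 9.46e-143, and adjusted p = 0.000591 with an estimated correlation). Of the DNA damage response list, 30 of 39 measured members fell and 2 rose (31 and 2 adjusted over the list alone), with Exo1 at -2.09 and Rad54l at -1.78 (adjusted p = 7.66e-19, and adjusted p = 0.000561 with an estimated correlation). Lysosome and autophagy genes went the other way. Of that list 27 of 47 measured members rose and 0 fell (29 and 2 adjusted over the list alone), with cathepsin L (Ctsl) at 0.69 and Lamp2 at 0.73 (adjusted p = 4.29e-14, and adjusted p = 0.0193 with an estimated correlation). The p53 target list was called higher, with 9 of 33 measured members higher and 5 lower (9 and 5 adjusted over the list alone, adjusted p = 0.00949, and adjusted p = 0.0367 with an estimated correlation). Members that rose were Btg2, an antiproliferative gene (1.22), and Trp53inp1 (1.19), while Cdkn1a, which encodes the cell cycle inhibitor p21, did not pass (-0.14, adjusted p = 0.351). In the ERK output list, 6 of 31 measured members rose and 7 fell (6 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.836). Targets of YAP and TEAD, transcription factors that respond to adhesion and cell shape, were called higher, and 8 of 25 measured members rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 0.009), but not with the other setting (adjusted p = 0.163 with an estimated correlation). Their members Ccn1 (0.94) and Ankrd1 (0.63) rose and F3 fell (-0.76). Of the focal adhesion list 8 of 38 measured members rose and 7 fell (9 and 9 adjusted over the list alone), and the list was not called (adjusted p = 0.409). Cholesterol synthesis genes fell widely, with 21 of 26 measured members lower and 1 higher (22 and 1 adjusted over the list alone, adjusted p = 3.57e-09, and adjusted p = 0.132 with an estimated correlation). The classical and gastric list was also called lower (11 of 28 measured members fell and 1 rose, with 13 and 3 adjusted over the list alone, adjusted p = 0.00792, and adjusted p = 0.0652 with an estimated correlation). In all, 4345 of 16747 genes tested passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1949 higher and 2396 lower, and 762 of them differed at least 2-fold, 154 higher and 608 lower.

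The second comparison asked what MEKi alone did. Transcripts downstream of ERK fell, as did those of replication and division. Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489, plus strand, GRCm38/mm10) dropped from 359 ± 3.82 to 55.8 ± 7.46 CPM, a change of -2.69 (SE 0.12). The ETS gene Etv4 changed by -3.95 (SE 0.25), the immediate early gene Egr1 by -3.48 (SE 0.15), the AP-1 gene Fosl1 by -3.91 (SE 0.19) and Myc by -1.88 (SE 0.10). Among the largest rises were Islr (5.76, SE 0.40), the alkaline phosphatase gene Alpl (5.24, SE 0.25), Igfbp5, which encodes a binding protein of insulin-like growth factors (5.23, SE 0.22), and the fibroblast growth factor receptor gene Fgfr3 (4.40, SE 0.22). Fgfr2 rose from 2.12 ± 0.681 to 34.1 ± 2.10 CPM (3.99, SE 0.19). Large falls included the secretogranin gene Scg2 (-5.48, SE 0.33), the G protein regulator gene Rgs16 (-5.12, SE 0.21) and the stromelysin gene Mmp10 (-4.70, SE 0.14). Scg2 lay under the floor in MEKi replicate 2 (0.0865 CPM), so the size of its fall is uncertain. The collagenase gene Mmp1a stood at 6.47 CPM in vehicle organoids and at 0.0319 CPM with MEKi, under the floor, so no fold is given.

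Of the ERK output list 28 of 31 measured members fell (28 adjusted over the list alone) and 0 rose, including the EGFR ligand genes Areg (-3.05) and Hbegf (-1.60) (camera, adjusted p = 1.72e-21, and adjusted p = 0.0386 with an estimated correlation). Among DNA replication genes, 49 of 51 measured members fell and 1 rose (50 and 1 adjusted over the list alone, adjusted p = 1e-28, and adjusted p = 0.0357 with an estimated correlation). Uhrf1, which maintains DNA methylation, changed by -2.59. In the mitosis list, 49 of 50 measured members fell (49 adjusted over the list alone, adjusted p = 1.71e-43, and adjusted p = 0.0437 with an estimated correlation). Ube2c changed by -2.56 and Mki67 by -1.96. Further lists were called with the preset correlation alone. In the interferon response list, 29 of 45 measured members rose and 1 fell (30 and 1 adjusted over the list alone, adjusted p = 2.78e-05, and adjusted p = 0.291 with an estimated correlation). Ifi27l2a changed by 3.01 and Irgm1, an interferon-induced GTPase gene, by 1.20. Antigen presentation genes went the same way, and 13 of 22 measured members rose (13 adjusted over the list alone) with 0 falling (adjusted p = 0.00207, and adjusted p = 0.198 with an estimated correlation), among them Tapbp, which encodes tapasin (1.07), and the class I gene H2-K1 (0.88), a family whose members share reads. Focal adhesion genes were lower, with 6 of 38 measured members higher and 20 lower (6 and 20 adjusted over the list alone, adjusted p = 0.0055, and adjusted p = 0.198 with an estimated correlation), and integrin alpha 2 (Itga2) at -2.21 and Ptk2 fell. Of the gemcitabine handling list, 6 of 23 measured members rose and 14 fell (7 and 14 adjusted over the list alone, adjusted p = 0.00444, and adjusted p = 0.222 with an estimated correlation), and Slc29a1, the nucleoside transporter that carries gemcitabine into cells, changed by -1.13 (SE 0.07). Fibroblast markers were called higher, with 8 of 12 measured members higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.000352, and adjusted p = 0.0669 with an estimated correlation). They included the chemokine gene Cxcl12 (3.30, from 97.3 ± 0.365 to 960.3 ± 113 CPM) and Col6a2 (1.30), both already present in vehicle organoids. Beside them, the share of counts on mitochondrial transcripts lay between 1.58% and 1.71% in the vehicle libraries and between 2.36% and 2.60% in the MEKi libraries. As TPM shares, the means were 3.641% and 5.091%.

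Single genes of other groups changed as well. The endoderm transcription factor gene Gata6, a marker of the classical PDAC subtype, rose from 17.5 ± 1.69 to 49.8 ± 5.80 CPM, while its list was not called (14 of 28 measured members rose and 6 fell, with 15 and 6 adjusted over the list alone, adjusted p = 0.0825). That list was called without a count filter (adjusted p = 0.0277) and with fry (adjusted p = 1.36e-06). The proapoptotic gene Bmf rose (2.05, SE 0.10), Bcl2l11, which encodes BIM, rose (0.67, SE 0.07), and Bcl2l1, which encodes BCL-XL, fell (-0.87, SE 0.08). Keratin genes Krt18 (-1.69) and Krt7 (-1.53) fell, and the epithelial and ductal list was not called (13 of 28 measured members rose and 9 fell, with 13 and 9 adjusted over the list alone, adjusted p = 0.913). The p53 target list, the YAP and TEAD list and the extracellular matrix list held members that went both ways and were not called (adjusted p = 0.913 for p53 targets, adjusted p = 0.913 for YAP and TEAD targets, and adjusted p = 0.944 for matrix genes). The median of the matrix list was below 0 (-0.21) and its mean above it (0.03), and the p53 target list showed the same split (median -0.04, mean 0.05). Trp53 itself changed by -0.50 (SE 0.11). In this comparison 9109 of 16747 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg), 4573 higher and 4536 lower, and 2967 differed at least 2-fold, 1591 higher and 1376 lower. The share higher was 50.2%, and 49.5% with RLE size factors.

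**Figure D2:**
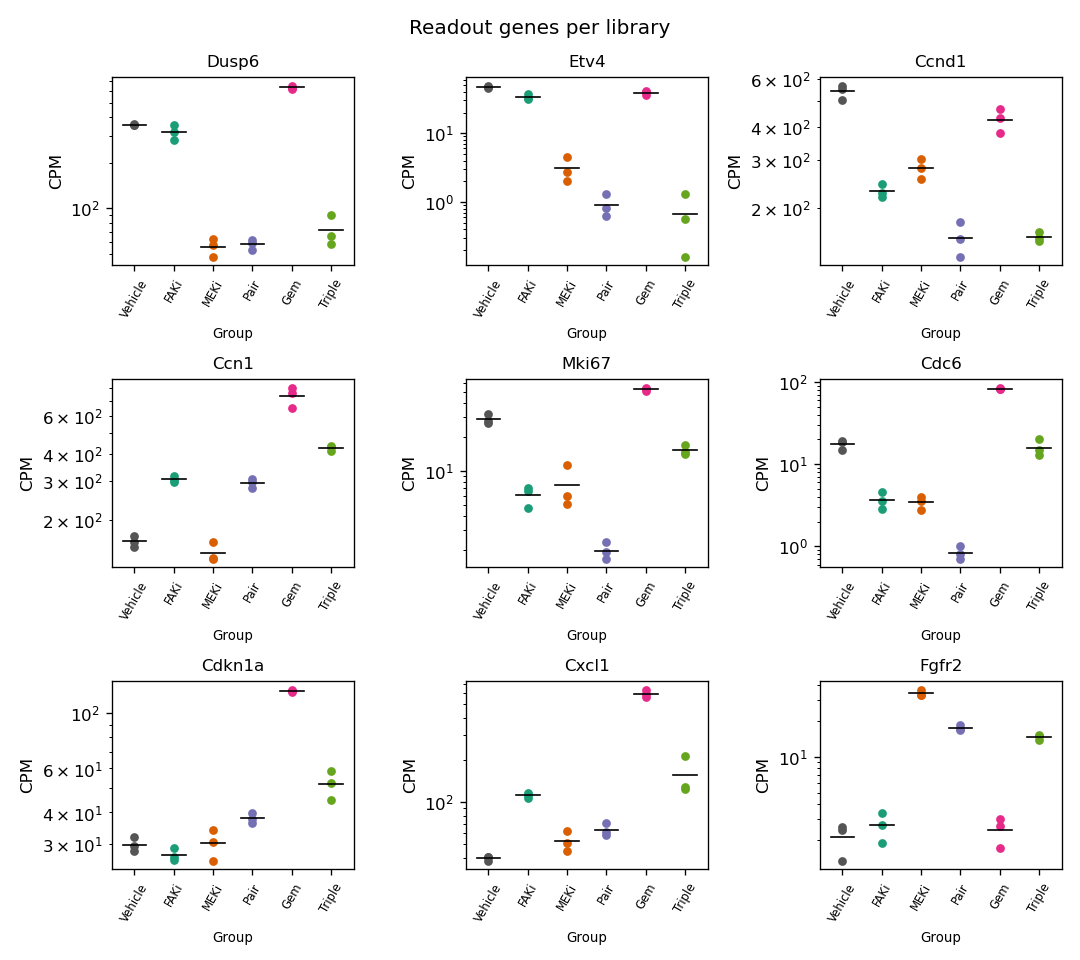
CPM on a log axis for 9 genes in the 6 groups, with 1 point per library and a bar at the mean of the 3 libraries. Dusp6 lies at 359 CPM in vehicle organoids and 55.8 CPM with MEKi, and Mki67 is lowest with the inhibitor pair, at 1.98 CPM.

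The third comparison set the inhibitor pair against vehicle. With both inhibitors, cell division genes and ERK readouts were lower than in vehicle organoids. Mki67 went from 29.0 ± 2.85 to 1.98 ± 0.347 CPM (-3.88, SE 0.23), Plk1, a mitotic kinase gene, changed by -3.87 (SE 0.13), Etv4 by -5.71 (SE 0.29), Etv5 by -4.57 (SE 0.28) and Ccnd1 by -1.81 (SE 0.09). Dusp6 changed by -2.63 (SE 0.12) and Egr1 by -3.41 (SE 0.15). The largest rises included the steroid synthesis gene Cyp11a1 (4.17, SE 0.27), the WNT ligand gene Wnt4 (4.05, SE 0.25), the angiotensinogen gene Agt (3.85, SE 0.11), the chemokine gene Cxcl15 (3.57, SE 0.23) and Fgfr3 (3.40, SE 0.22). Has2, a hyaluronan synthase gene, was among the largest falls (-5.19, SE 0.23). Pdyn, Mmp1a and Tmem132c stood at 0.0261, 0.0657 and 0.102 CPM with the pair, under the floor for Pdyn and Mmp1a and at it for Tmem132c, and no fold is given for them.

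In the ERK output list, 30 of 31 measured members fell (31 adjusted over the list alone, adjusted p = 4.01e-21, and adjusted p = 0.0205 with an estimated correlation). DNA replication genes behaved alike, and 50 of 51 measured members fell (50 adjusted over the list alone, adjusted p = 3.64e-51, and adjusted p = 0.0039 with an estimated correlation). Mcm5 changed by -3.46 and Uhrf1 by -3.60. Of the mitosis genes, 49 of 50 measured members fell (49 adjusted over the list alone), with a median of -3.23 (adjusted p = 2.17e-90, and adjusted p = 0.00765 with an estimated correlation), Ube2c at -3.97 and Kif2c at -3.43. Of the DNA damage response list, 27 of 39 measured members fell and 7 rose (28 and 7 adjusted over the list alone, adjusted p = 8.68e-09, and adjusted p = 0.0186 with an estimated correlation). Timeless, which protects replication forks, changed by -2.27. Ribosomal protein genes fell widely but by less. Of that list 83 of 88 measured members fell (83 adjusted over the list alone), with a median of -0.69 (adjusted p = 8.54e-29, and adjusted p = 0.183 with an estimated correlation), and Rpsa at -1.03. Their share of counts was 6.30% ± 0.205 in vehicle organoids and 4.46% ± 0.0207 with the pair. Several lists were called higher with the preset correlation alone. Fibroblast markers were among them (6 of 12 measured members rose and 3 fell, with 6 and 3 adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.153 with an estimated correlation). So were mitochondrial transcripts (10 of 17 rose and 0 fell, with 11 and 0 adjusted over the list alone, adjusted p = 0.0263, and adjusted p = 0.517 with an estimated correlation). Their share of counts was 1.65% in vehicle organoids and 2.27% with the pair. For lysosome and autophagy genes, 29 of 47 measured members rose and 4 fell (29 and 4 adjusted over the list alone, adjusted p = 4.29e-07, and adjusted p = 0.131 with an estimated correlation). Lamp2 changed by 1.21. For interferon response genes, 23 of 45 measured members rose and 3 fell (23 and 3 adjusted over the list alone, adjusted p = 0.0148, and adjusted p = 0.517 with an estimated correlation). Ifih1, an RNA sensor gene, changed by 1.11. Antigen presentation genes fell short of the call as a list (adjusted p = 0.0651), but were called without a count filter (adjusted p = 0.0149) and with fry (adjusted p = 2.18e-05), and 12 of 22 measured members rose and 3 fell (12 and 3 adjusted over the list alone), including B2m (0.49). Ccn1, a YAP target, rose (0.89, SE 0.07) while its list was called only with fry (adjusted p = 0.397, and adjusted p = 0.0108 with fry). The proapoptotic genes Bmf (2.44) and Pmaip1, which encodes NOXA (1.53), rose. Of 16747 genes, 8874 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 4597 higher and 4277 lower, and 2671 differed at least 2-fold. The share higher was 51.8%, but 47.9% with RLE size factors and 48% with DESeq2, so the larger direction depends on the scaling.

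What FAKi added to MEKi was asked by comparing the pair with MEKi alone. Cell division genes were lower still with the pair, ERK phosphatase readouts were not, and several of the largest MEKi-induced genes were lower. Mki67 stood at 7.48 ± 3.31 CPM with MEKi and 1.98 ± 0.347 CPM with the pair (-1.92, SE 0.24), and Ccnd1 changed by -0.86 (SE 0.09). Dusp6 differed by 0.05 (adjusted p = 0.808) and Fosl1 by 0.14 (adjusted p = 0.683), neither past the test, whereas Etv4 (-1.76, SE 0.34) and Etv5 (-2.39, SE 0.28) fell. The largest rises included Dusp1, a phosphatase gene of MAP kinases (2.31, SE 0.38), Try5 (2.29, SE 0.13), Mmp10 (1.95, SE 0.14) and the prostaglandin synthase gene Ptgs2 (1.59, SE 0.15). The largest falls were the proenkephalin gene Penk (-3.87, SE 0.24), Islr (-2.93, SE 0.30), Igfbp5 (-2.77, SE 0.18) and Alpl (-2.62, SE 0.20).

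Among mitosis genes, 46 of 50 measured members fell and 0 rose (49 and 1 adjusted over the list alone, adjusted p = 6.97e-57, and adjusted p = 0.0307 with an estimated correlation). Plk1 changed by -1.61 and Ccnb2, which encodes cyclin B2, by -1.52. Of the replication genes, 35 of 51 measured members fell (38 adjusted over the list alone, adjusted p = 1.16e-18, and adjusted p = 0.0468 with an estimated correlation). The origin licensing gene Cdc6 changed by -2.05. Classical and gastric genes were called lower, with 10 of 28 measured members lower and 0 higher (12 and 1 adjusted over the list alone, adjusted p = 1.72e-05, and adjusted p = 0.0232 with an estimated correlation), among them Ctse (-0.69), Lgals4 (-0.70) and Dmbt1 (-1.15). Gata6 was also lower (-0.69, SE 0.11). Heat shock genes rose, with 10 of 17 measured members higher and 1 lower (10 and 1 adjusted over the list alone, adjusted p = 7.3e-05, and adjusted p = 0.0307 with an estimated correlation), including Hspa4l (0.90) and Hsph1 (0.64). For p53 targets, 9 of 33 measured members rose and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.0132, and adjusted p = 0.0484 with an estimated correlation). Gdf15 changed by 1.51 and Ddit4l by -1.20. The YAP and TEAD list was called higher with the preset correlation (7 of 25 measured members rose and 2 fell, with 8 and 3 adjusted over the list alone, adjusted p = 0.0152) and lost with the other setting (adjusted p = 0.193 with an estimated correlation), and its members Ccn1 (1.06) and Ankrd1 (0.73) rose. Focal adhesion genes were also called higher (14 of 38 measured members rose and 3 fell, with 15 and 3 adjusted over the list alone, adjusted p = 0.00338, and adjusted p = 0.113 with an estimated correlation). Zyxin (Zyx) changed by 0.76 and vinculin (Vcl) by 0.63. In the interferon response list, 8 of 45 measured members fell (7 adjusted over the list alone, adjusted p = 0.000299, and adjusted p = 0.362 with an estimated correlation). Basal-like genes were called lower (2 of 22 measured members rose and 11 fell, with 2 and 12 adjusted over the list alone, adjusted p = 0.000353, and adjusted p = 0.113 with an estimated correlation). The ERK output list was not called (6 of 31 measured members rose and 5 fell, with 6 and 7 adjusted over the list alone, adjusted p = 0.72). Of 16747 genes, 3442 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 1561 higher and 1881 lower, and 549 differed at least 2-fold, 83 higher and 466 lower. The share higher was 45.4%, and 36.1% with RLE size factors.

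The converse, what MEKi added to FAKi, came from the pair against FAKi alone. ERK readouts were lower with the pair, as were Myc (-1.40, SE 0.10) and Phlda1 (-0.78, SE 0.11). Dusp6 stood at 320.0 ± 34.2 CPM with FAKi and 57.8 ± 4.43 CPM with the pair (-2.47, SE 0.12). Etv4 (-5.22, SE 0.29), Egr1 (-3.90, SE 0.15) and Fosl1 (-3.18, SE 0.19) fell. The largest rises were the ketone body synthesis gene Hmgcs2 (4.03, SE 0.11), the transthyretin gene Ttr (3.84, SE 0.15), the secreted inhibitor gene Spink4 (3.75, SE 0.17) and Fgfr3 (3.48, SE 0.22). Of the ERK output list, 29 of 31 measured members fell (29 adjusted over the list alone, adjusted p = 5.65e-29, and adjusted p = 0.022 with an estimated correlation), the only list of the 31 called here with the estimated correlation. Mitosis (49 of 50 measured members fell and 1 rose, with 49 and 1 adjusted over the list alone, adjusted p = 1.68e-20, and adjusted p = 0.269 with an estimated correlation) and DNA replication genes (39 of 51 measured members fell and 2 rose, with 40 and 2 adjusted over the list alone, adjusted p = 1.27e-10, and adjusted p = 0.227 with an estimated correlation) were called with the preset correlation alone, with Plk1 at -1.66 and Uhrf1 at -1.92. Interferon response genes were likewise called higher (23 of 45 measured members rose, with 23 adjusted over the list alone, adjusted p = 0.000119, and adjusted p = 0.32 with an estimated correlation). The RNA sensor gene Ddx58 changed by 1.45. Antigen presentation genes followed (12 of 22 measured members rose and 1 fell, with 12 and 2 adjusted over the list alone, adjusted p = 0.0361, and adjusted p = 0.32 with an estimated correlation). Rrm2, which encodes the gemcitabine-relevant reductase subunit, did not differ past the test (-0.05, adjusted p = 0.676), and neither did Ccn1 (-0.06, adjusted p = 0.577). Of 16747 genes, 7722 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 3985 higher and 3737 lower. The share higher was 51.6%, but 46.8% with RLE size factors and 46.7% with DESeq2, so the larger direction depends on the scaling.

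**Figure D3:**
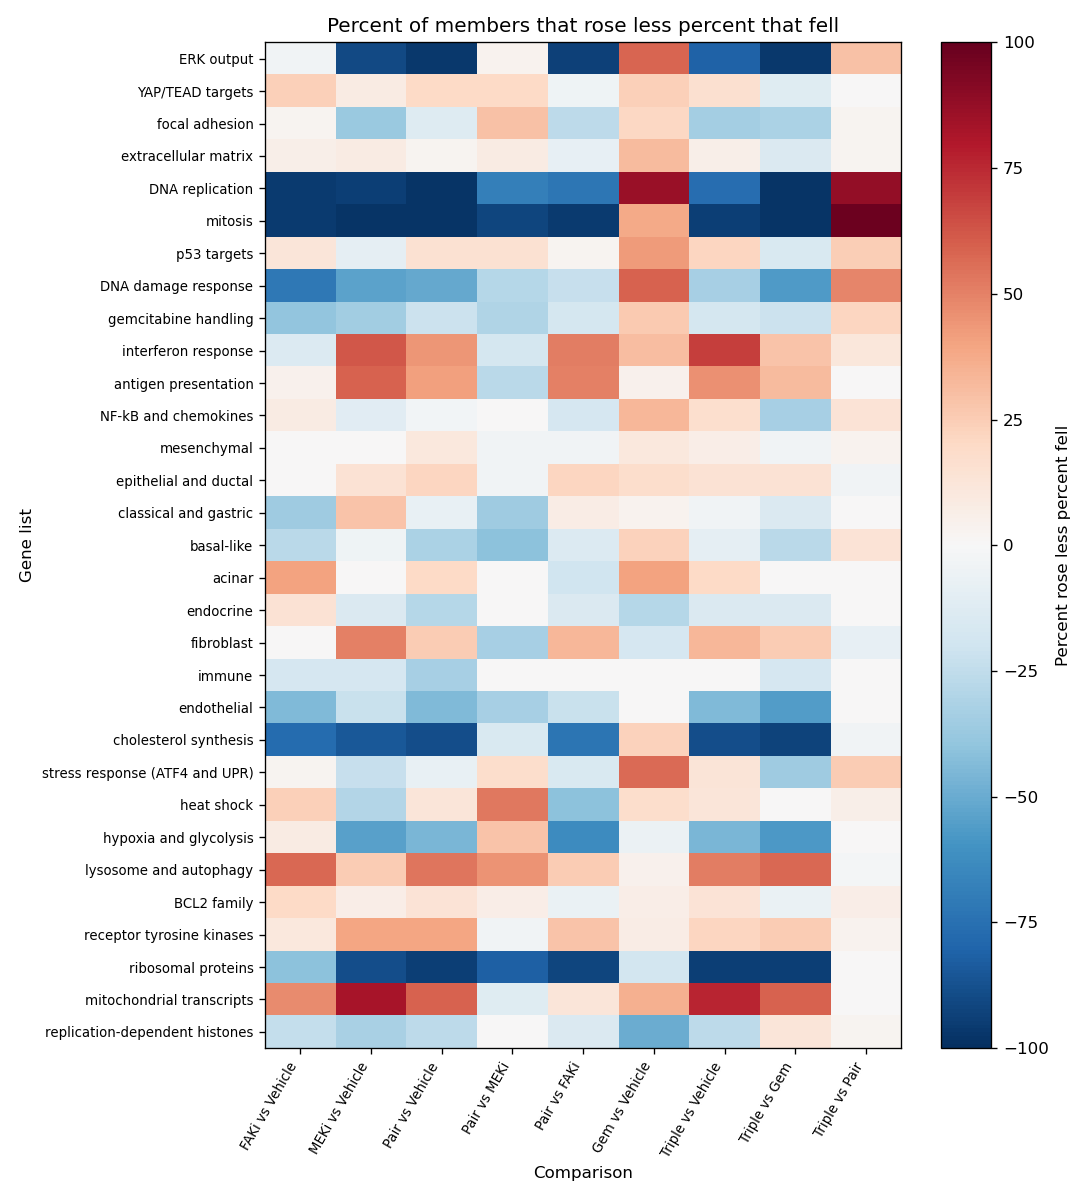
Percent of the measured members that rose less the percent that fell, for the 31 gene lists (rows) in the 9 comparisons of groups (columns), on a colour scale from blue (every member fell) to red (every member rose). The mitosis and DNA replication rows are blue in each comparison of an inhibitor with vehicle and red in the comparison of the triple combination with the inhibitor pair.

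Gemcitabine alone was compared with vehicle. It raised several chemokine and cytokine genes, replication genes, and some stress and p53 target genes, while many replication-dependent histone genes fell. The T cell attracting chemokine gene Cxcl10 went from 1.07 ± 0.153 to 79.7 ± 3.03 CPM (6.22, SE 0.18) and Csf2, which encodes the growth factor GM-CSF, from 11.6 ± 0.616 to 853 ± 54.8 CPM (6.21, SE 0.23). The neutrophil attracting chemokine gene Cxcl1 rose by 3.91 (SE 0.16), Ccl20 by 4.65 (SE 0.25) and the endothelin gene Edn1 by 4.29 (SE 0.26). Cxcl2, a close relative of Cxcl1, stood at 0.0475 CPM in vehicle organoids, under the floor, and at 7.35 CPM with gemcitabine. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, plus strand, GRCm38/mm10) rose from 29.7 ± 2.06 to 123 ± 1.28 CPM (2.05, SE 0.10). Among the largest falls were Hist1h1e (-2.11, SE 0.17), Hist1h2ap (-1.99, SE 0.16) and, outside the replication-dependent group, H1f0 (-1.47, SE 0.07). Replication-dependent histone genes are near-identical copies whose reads can be split between members.

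Of the replication-dependent histone list, 17 of 34 measured members fell (18 adjusted over the list alone) and 0 rose (adjusted p = 2.36e-13, and adjusted p = 0.000762 with an estimated correlation). Histone transcripts made up 0.0410% ± 0.001 of counts in vehicle organoids and 0.0203% ± 0.00210 with gemcitabine, and 0.09567% and 0.04433% as TPM shares. By contrast, in the DNA replication list, 44 of 51 measured members rose and 0 fell (45 and 1 adjusted over the list alone, adjusted p = 4.22e-46, and adjusted p = 0.00125 with an estimated correlation). The cyclin E gene Ccne2 changed by 2.35, Cdc6 by 2.24 and the histone stem-loop binding gene Slbp by 1.43. For the DNA damage response, 24 of 39 measured members rose and 1 fell (27 and 1 adjusted over the list alone, adjusted p = 2.51e-13, and adjusted p = 0.00128 with an estimated correlation). Gadd45b changed by 2.28 and Gadd45g by 2.08. The p53 target list was called higher, and 17 of 33 measured members rose and 3 fell (18 and 5 adjusted over the list alone, adjusted p = 2.36e-13, and adjusted p = 4.89e-05 with an estimated correlation). The kinase gene Plk2 changed by 2.75 and Gdf15 by 3.62. Mdm2, a p53 target that encodes its ubiquitin ligase, changed by 0.43 (SE 0.07). In the list of ATF4 and unfolded protein stress genes, 23 of 39 measured members rose and 1 fell (23 and 1 adjusted over the list alone, adjusted p = 1.27e-16, and adjusted p = 0.00125 with an estimated correlation), including Atf3 (3.63), Atf4 (1.52) and Ddit3 (1.55). Of NF-kB and chemokine genes, 14 of 36 measured members rose and 2 fell (14 and 2 adjusted over the list alone, adjusted p = 1.9e-13, and adjusted p = 0.00461 with an estimated correlation), among them Tnfaip3, a feedback inhibitor of NF-kB (1.89). ERK output genes rose, with 20 of 31 measured members higher and 2 lower (21 and 2 adjusted over the list alone, adjusted p = 9.13e-26, and adjusted p = 0.00544 with an estimated correlation), including Egr1 (2.19), Lif (2.80) and Dusp6 (0.82). Of YAP and TEAD targets, 7 of 25 measured members rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 4.33e-05, and adjusted p = 0.0417 with an estimated correlation), led by Ccn1 (2.21) and Ankrd1 (1.28).

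Mitosis genes were called higher with the preset correlation, with 22 of 50 measured members higher and 3 lower (24 and 4 adjusted over the list alone, adjusted p = 0.00171), but not with the other setting (adjusted p = 0.653 with an estimated correlation) or with fry (adjusted p = 0.0605), and Plk1 (-0.64) fell while Cep55 (1.42) rose. Genes of gemcitabine handling included Rrm2 (1.64, SE 0.09), Rrm1 (1.10, SE 0.09) and Dck, the kinase that activates gemcitabine (1.22, SE 0.12), which rose. For their list, 7 of 23 measured members rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.00462, and adjusted p = 0.264 with an estimated correlation). Interferon response genes were called higher with the preset correlation alone (14 of 45 measured members rose and 0 fell, with 19 and 1 adjusted over the list alone, adjusted p = 4.86e-05, and adjusted p = 0.39 with an estimated correlation). Isg15 changed by 2.07. Matrix genes were called the same way (12 of 35 measured members rose and 1 fell, with 14 and 1 adjusted over the list alone, adjusted p = 5.83e-06, and adjusted p = 0.0517 with an estimated correlation). Serpine1, which encodes the inhibitor PAI-1, changed by 1.53 and tenascin C (Tnc) by 1.32. The basal-like list was called higher (5 of 22 measured members rose, with 5 adjusted over the list alone, adjusted p = 0.00994, and adjusted p = 0.27 with an estimated correlation). The proapoptotic genes Bcl2l11 (1.31, SE 0.07) and Pmaip1 (1.83, SE 0.13) and the antiapoptotic gene Mcl1 (0.60, SE 0.10) rose. Myc rose (1.51, SE 0.10), as did Ptk2 (0.43, SE 0.07), the gene of the FAKi target. Of 16747 genes, 4156 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 2381 higher and 1775 lower, and 587 differed at least 2-fold, 495 higher and 92 lower.

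Against vehicle, the triple combination showed low ERK readouts together with high Cxcl10. Cxcl10 rose to 81.6 ± 16.9 CPM (6.25, SE 0.18) and Ccl20 by 3.93 (SE 0.25), while Dusp6 (-2.33, SE 0.12), Etv4 (-6.14, SE 0.30) and Fosl1 (-3.03, SE 0.18) fell. Wnt4 (3.81, SE 0.25), Agt (3.66, SE 0.11) and Fgfr3 (3.17, SE 0.22) were among the largest rises and Scg2 (-4.60, SE 0.30) among the largest falls. Mki67 changed by -0.93 (SE 0.18), Cdkn1a by 0.81 (SE 0.10) and Pmaip1 by 2.23 (SE 0.13), whereas Dck did not pass (0.03, adjusted p = 0.873). No list was called here with the estimated correlation. With the preset correlation, ERK output (26 of 31 measured members fell and 1 rose, with 27 and 1 adjusted over the list alone, adjusted p = 2.7e-16, and adjusted p = 0.0803 with an estimated correlation), mitosis (48 of 50 measured members fell and 1 rose, with 48 and 1 adjusted over the list alone, adjusted p = 2.75e-18, and adjusted p = 0.184 with an estimated correlation) and DNA replication (39 of 51 measured members fell and 0 rose, with 39 and 1 adjusted over the list alone, adjusted p = 8.26e-11, and adjusted p = 0.127 with an estimated correlation) were lower. Interferon response genes were called higher (33 of 45 measured members rose and 2 fell, with 33 and 2 adjusted over the list alone, adjusted p = 5.35e-06, and adjusted p = 0.293 with an estimated correlation), as were antigen presentation genes (11 of 22 measured members rose and 1 fell, with 11 and 1 adjusted over the list alone, adjusted p = 0.0311, and adjusted p = 0.293 with an estimated correlation) and p53 targets (16 of 33 measured members rose and 9 fell, with 17 and 10 adjusted over the list alone, adjusted p = 0.00381, and adjusted p = 0.0803 with an estimated correlation). Tapbp changed by 0.93, B2m by 0.58 and Plk2 by 1.85. Cd274, which encodes the immune checkpoint ligand PD-L1, changed by 0.99 (SE 0.28), at 3.32 ± 0.558 CPM. Of 16747 genes, 8374 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 4225 higher and 4149 lower, and 2235 differed at least 2-fold. The share higher was 50.5%, but 47.7% with RLE size factors.

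The comparison of the triple combination with gemcitabine asked what the inhibitor pair changed in gemcitabine-treated organoids. ERK readout and replication genes were lower with the pair present, as were some cytokine genes, but Cxcl10 was not (79.7 ± 3.03 and 81.6 ± 16.9 CPM). Csf2 stood at 853 ± 54.8 CPM with gemcitabine and 14.3 ± 7.93 CPM with the triple combination (-5.91, SE 0.23), and Has2 (-5.79, SE 0.19), Myc (-2.23, SE 0.10), Cdkn1a (-1.24, SE 0.10) and Dck (-1.20, SE 0.11) were lower. Serpinb2 stood at 10.1 and 0.0423 CPM, the second under the floor. Rises included Wnt4 (4.74, SE 0.28), Agt (3.80, SE 0.11), Cyp11a1 (3.73, SE 0.26) and Hmgcs2 (2.73, SE 0.10). Of the ERK output list, 30 of 31 measured members fell (30 adjusted over the list alone, adjusted p = 5.05e-38, and adjusted p = 0.00398 with an estimated correlation). Egr1 changed by -4.27 and Hbegf by -2.53. Of the replication genes, 50 of 51 measured members fell (50 adjusted over the list alone, adjusted p = 7.15e-42, and adjusted p = 0.00398 with an estimated correlation). Dut, which removes dUTP, changed by -2.15. Of the DNA damage response genes, 26 of 39 measured members fell and 4 rose (27 and 4 adjusted over the list alone, adjusted p = 6.18e-07, and adjusted p = 0.0266 with an estimated correlation). Mitosis genes were called lower with the preset correlation (49 of 50 measured members fell, with 49 adjusted over the list alone, adjusted p = 3.44e-23, and adjusted p = 0.12 with an estimated correlation). Survivin (Birc5) changed by -2.05. NF-kB and chemokine genes were also called lower with that setting (7 of 36 measured members rose and 19 fell, with 7 and 19 adjusted over the list alone, adjusted p = 0.00227, and adjusted p = 0.144 with an estimated correlation), although Cxcl12 rose (2.35). Of 16747 genes, 9068 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 4397 higher and 4671 lower, and 2704 differed at least 2-fold.

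What gemcitabine added to the inhibitor pair was the smallest of the comparisons between groups by count, and it was nearly all upward. Cell cycle genes stood higher in the triple combination than with the pair. Mki67 went from 1.98 ± 0.347 to 15.3 ± 1.52 CPM (2.96, SE 0.23), and Cdc6 (ENSMUSG00000017499, chromosome 11, 98907801 to 98923940, plus strand, GRCm38/mm10) from 0.835 ± 0.150 to 15.9 ± 3.74 CPM (4.25, SE 0.21). Cxcl10 showed the largest rise (6.39, SE 0.18, from 0.947 ± 0.336 CPM), followed by the DNA glycosylase gene Neil3 (4.64, SE 0.34). Neil3 lay under the floor in FAKi+MEKi replicate 2 (0.0669 CPM), so the size of its rise is uncertain. Pclaf (3.81, SE 0.22), Csf2 (3.42, SE 0.29), the kinase gene Pbk (3.24, SE 0.18), the cohesion gene Esco2 (3.06, SE 0.23) and Exo1 (2.94, SE 0.20) also rose. Falls included the potassium channel gene Kcnj11 (-0.92, SE 0.21), Lrrc61 (-0.80, SE 0.15) and Cul9 (-0.70, SE 0.17). Kcnj11 no longer passed without FAKi+MEKi replicate 2 (adjusted p = 0.0959) or Gemcitabine+FAKi+MEKi replicate 2 (adjusted p = 0.0765). Cul9 no longer passed with an effective-length offset (adjusted p = 0.276), or without FAKi+MEKi replicate 1 or 2 or Gemcitabine+FAKi+MEKi replicate 1 (adjusted p = 0.0691 to 0.15).

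In the mitosis list, 49 of 50 measured members rose (49 adjusted over the list alone) and 0 fell (adjusted p = 8.96e-06 with an estimated correlation), with a median of 2.14, Nusap1 at 2.68 and Kif2c at 2.20. Of the replication genes, 45 of 51 measured members rose (50 adjusted over the list alone, adjusted p = 2.79e-160, and adjusted p = 8.96e-06 with an estimated correlation). Mcm5 changed by 2.72 and Ccne2 by 2.52. Of DNA damage response genes, 19 of 39 measured members rose (25 adjusted over the list alone, adjusted p = 9.35e-43, and adjusted p = 8.96e-06 with an estimated correlation), including Rad51, the recombinase gene (2.55), and Rad54l (2.39). Of the p53 targets, 8 of 33 measured members rose (10 adjusted over the list alone, adjusted p = 0.000121, and adjusted p = 0.00345 with an estimated correlation), with Plk2 at 1.06 and Cdkn1a at 0.46 (adjusted p = 0.0538 for Cdkn1a without Gemcitabine+FAKi+MEKi replicate 2). In the ATF4 and unfolded protein stress list, 10 of 39 measured members rose and 0 fell (15 and 1 adjusted over the list alone, adjusted p = 1.82e-11, and adjusted p = 0.0044 with an estimated correlation). Nupr1 changed by 0.88 and Atf4 by 0.85. Replication-dependent histone genes were not called (1 of 34 measured members rose and 0 fell, with 1 and 0 adjusted over the list alone, adjusted p = 0.926), and the median of that list was -0.08. Lists called with the preset correlation alone were ERK output (9 of 31 measured members rose and 0 fell, with 13 and 1 adjusted over the list alone, adjusted p = 1.43e-08, and adjusted p = 0.174 with an estimated correlation), interferon response (5 of 45 measured members rose, with 10 adjusted over the list alone, adjusted p = 4.55e-05, and adjusted p = 0.529 with an estimated correlation), NF-kB and chemokines (6 of 36 measured members rose and 1 fell, with 9 and 2 adjusted over the list alone, adjusted p = 0.000179, and adjusted p = 0.175 with an estimated correlation) and gemcitabine handling (5 of 23 measured members rose, with 5 adjusted over the list alone, adjusted p = 2.05e-05, and adjusted p = 0.101 with an estimated correlation). Dusp6 (0.30, adjusted p = 0.233) and Ccnd1 (0.02, adjusted p = 0.967) did not pass, though Dusp6 did without a count filter (adjusted p = 0.000105) and without Gemcitabine+FAKi+MEKi replicate 3 (adjusted p = 0.0392). Dck rose from 11.2 ± 0.972 to 22.4 ± 4.42 CPM. Of 16747 genes, 599 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 547 higher and 52 lower, and 270 differed at least 2-fold, 260 higher and 10 lower.

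**Figure D4:**
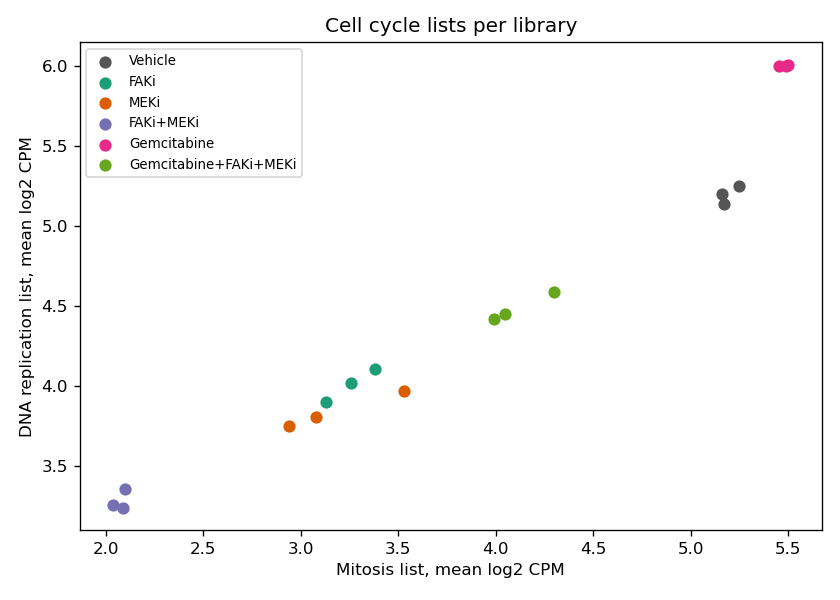
Mean log2 CPM of the DNA replication list (vertical axis) against that of the mitosis list (horizontal axis), with 1 point per library coloured by group. The inhibitor pair lies lowest on the mitosis axis, between 2.04 and 2.1, and the triple combination lies between 3.99 and 4.3.

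Whether the pair departed from the sum of the single inhibitor effects was tested by the interaction of FAKi and MEKi on the log2 scale. A value above 0 means that the pair stood higher than that sum. Replication genes fell by less than the sum. Many mitosis genes did too, but their list was not called with an estimated correlation. The mitotic kinesin gene Kifc1 had an interaction of 2.34 (SE 0.37), Rrm1 of 1.03 (SE 0.13) and Rrm2 of 0.90 (SE 0.13). Dusp1 (1.97, SE 0.51) and C1qbp (2.48, SE 0.69) also lay above the sum. Dusp1 no longer passed without Vehicle replicate 1, MEKi replicate 1 or 2, or FAKi+MEKi replicate 1 or 2 (adjusted p = 0.0567 to 0.0701). C1qbp no longer passed with an effective-length offset (adjusted p = 0.0509), or without Vehicle replicate 1 or 3, FAKi replicate 1 or 2, MEKi replicate 1 or 2, or FAKi+MEKi replicate 1 or 2 (adjusted p = 0.0565 to 0.101). Below the sum lay Clca3a2 (-3.02, SE 0.43), Ddit4l (-2.48, SE 0.21), Cxcl15 (-2.45, SE 0.31), Gata6 (-0.81, SE 0.16) and Etv5 (-1.29, SE 0.36). Etv5 no longer passed with DESeq2 (adjusted p = 0.0586), with an effective-length offset (adjusted p = 0.057), or without any replicate of Vehicle or FAKi+MEKi, FAKi replicate 1 or 2, or MEKi replicate 1 (adjusted p = 0.0514 to 0.0999). Dusp6 (0.22, adjusted p = 0.48) and Mki67 (0.31, adjusted p = 0.611) did not depart past the test. In the DNA replication list 29 of 51 measured members lay above the sum (38 adjusted over the list alone) and 0 below, with a median of 0.61 (camera, adjusted p = 5e-31, and adjusted p = 0.0248 with an estimated correlation). In the DNA damage response list 12 of 39 lay above (17 adjusted over the list alone) and 0 below, with a median of 0.46 (adjusted p = 6.38e-08, and adjusted p = 0.0248 with an estimated correlation). For mitosis, 31 of 50 lay above (42 adjusted over the list alone), with a median of 0.80 (adjusted p = 1.23e-32, and adjusted p = 0.135 with an estimated correlation). The interaction passed for 1171 of 16747 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 685 above and 486 below the sum. The share of these genes above the sum was 58.5%, but 50.3% with RLE size factors and 49.8% with DESeq2, so the excess above the sum depends on the scaling, and the cause was not tested. That count was 707 without Vehicle replicate 1, 774 without FAKi+MEKi replicate 1 and 779 without FAKi+MEKi replicate 2.

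Whether gemcitabine acted differently with the inhibitor pair present was tested in the same way. The gemcitabine effect on mitotic genes lay higher with the pair present, and that on some p53 targets, chemokines and histones differed too. Plk1 had an interaction of 2.66 (SE 0.17), Mki67 of 2.09 (SE 0.29), Neil3 of 3.06 (SE 0.42), the helicase gene Pif1 of 3.72 (SE 0.46) and the nuclease gene Ankle1 of 3.82 (SE 0.35). Levels with the pair were low, at 0.0669 to 0.837 CPM for Neil3, 0.130 to 0.870 CPM for Pif1 and 0.2576 to 0.2865 CPM for Ankle1. The lowest Neil3 value lies under the floor. On the negative side stood Nppb (-4.06, SE 0.94), which without FAKi+MEKi replicate 3 was -2.098 and did not pass (adjusted p = 0.551), Edn1 (-3.83, SE 0.35), the early response gene Egr2 (-3.47, SE 0.47), Ccl20 (-3.29, SE 0.32), Ccn1 (-1.69, SE 0.10), Cdkn1a (-1.59, SE 0.14) and Bcl2l11 (-1.18, SE 0.10). Rrm1 (0.02, adjusted p = 0.958), Rrm2 (-0.05, adjusted p = 0.899) and Dck (-0.23, adjusted p = 0.55) did not pass. In the mitosis list 48 of 50 measured members had a positive interaction (49 adjusted over the list alone), with a median of 1.84 (camera, adjusted p = 1.83e-194, and adjusted p = 0.000269 with an estimated correlation). In the histone list 11 of 34 were positive (13 adjusted over the list alone) and 0 negative, with a median of 0.87 (adjusted p = 7.52e-16, and adjusted p = 0.000269 with an estimated correlation). Of p53 targets, 7 of 33 were negative and 0 positive (10 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 1.45e-08, and adjusted p = 0.000269 with an estimated correlation). NF-kB and chemokine genes (10 of 36 negative, 11 adjusted over the list alone, median -0.21, adjusted p = 5.41e-09, and adjusted p = 0.0232 with an estimated correlation) followed. So did YAP and TEAD targets (5 of 25 negative, 7 adjusted over the list alone, median -0.20, adjusted p = 8.91e-08, and adjusted p = 0.0169 with an estimated correlation). Matrix genes (7 of 35 negative, 8 adjusted over the list alone, median -0.25, adjusted p = 1.74e-08, and adjusted p = 0.0235 with an estimated correlation) and stress genes (7 of 39 negative, 8 adjusted over the list alone, median -0.14, adjusted p = 5.68e-06, and adjusted p = 0.0401 with an estimated correlation) were also called. ERK output genes were called negative with the preset correlation alone (12 of 31, with 15 negative and 3 positive adjusted over the list alone, adjusted p = 1.26e-11, and adjusted p = 0.0595 with an estimated correlation). The interaction passed for 694 of 16747 genes (edgeR quasi-likelihood, Benjamini-Hochberg), 286 positive and 408 negative, and the count was 455 without Gemcitabine+FAKi+MEKi replicate 2. The positive share was 41.2%, and 47.3% with RLE size factors.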

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

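The results in this part stood out because a test of the difference between effects, an interaction, passed. The tests of library scaling, of working p53 and of signalling that the inhibitor pair blocks were chosen only after the result was seen, and the others were written before.

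The FAKi effect differed with and without MEKi for 1171 genes. The largest differences between these effects were those of C1qbp (2.48), Kifc1 (2.34), Chd5 (2.11), Dusp1 (1.97) and Lat2 (1.84) above the sum of the single effects, and Clca3a2 (-3.02), Ddit4l (-2.48), Cxcl15 (-2.45), Alpl (-2.14) and Rflna (-2) below it. The list medians that differed were 0.613 for DNA replication and 0.461 for the DNA damage response. C1qbp no longer passed with an effective-length offset (adjusted p = 0.0509), or without Vehicle replicate 1 or 3, FAKi replicate 1 or 2, MEKi replicate 1 or 2, or FAKi+MEKi replicate 1 or 2 (adjusted p = 0.0565 to 0.101). Chd5 was 1.222 with that offset and no longer passed (adjusted p = 0.28). Dusp1 no longer passed without Vehicle replicate 1, MEKi replicate 1 or 2, or FAKi+MEKi replicate 1 or 2 (adjusted p = 0.0567 to 0.0701). Of 100 groupings of the libraries, with the real one counted among them, 8 gave at least 1171 genes, and the highest other gave 4640. That is several times the real count and points to a structure of the samples, since regroupings mix groups with large main effects. These counts therefore neither exclude chance nor support it.

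The gemcitabine effect differed with and without the inhibitor pair for 694 genes. The largest differences were those of Ankle1 (3.82), Pif1 (3.72), Neil3 (3.06), Psrc1 (2.77) and Plk1 (2.66) upward, and Nppb (-4.06), Tmem95 (-3.99), Edn1 (-3.83), Egr2 (-3.47) and Ccl20 (-3.30) downward. The list medians that differed were 1.841 for mitosis, 0.868 for replication-dependent histones, -0.199 for YAP and TEAD targets, -0.254 for the extracellular matrix, -0.185 for p53 targets, -0.209 for NF-kB and chemokines and -0.145 for stress genes. Nppb lay under the floor in 2 of the 3 pair libraries (0.0322 and 0.0669 CPM). Without FAKi+MEKi replicate 3 it was -2.098 and did not pass (adjusted p = 0.551), and the cause was not tested. Neil3 lay under the floor in FAKi+MEKi replicate 2 (0.0669 CPM). Of 100 groupings, again with the real one counted, 7 gave at least 694 genes, and the highest other gave 5348, from the same structure of the samples. These counts again leave chance neither excluded nor supported.

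Mitosis genes stood higher in the triple combination than with the inhibitor pair, and 3 technical explanations were tested. The log2 ratio of the mean TMM factors of the groups was -0.0005, with factors of 1.061 to 1.067 in the triple combination and 1.056 to 1.072 in the pair. The factors applied therefore did not produce the difference. Factors of all 18 libraries lay between 0.911 and 1.072, so no other groups would have differed much by this measure either. The list median lay 2.165 above that of all genes. A scaling error shifts all genes alike, so this value argues against library scaling. The median log2 fold change of the list was 2.142 before and 2.155 after a trend on GC content and effective length was removed. The quartiles after removal were 1.719 and 2.454, for 50 of 50 members with a GC value. The fitted trend had an SD of 0.039 over genes, small beside that median, which argues against that bias. The lowest library of the triple combination lay 1.892 above the highest library of the pair in mean log2 CPM of the list, with a range of 0.307 within the triple combination and 0.06 within the pair, so a library exchanged between the groups does not explain it. No biological explanation was tested.

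Of p53 targets, 17 of 33 measured members rose and 3 fell with gemcitabine, in organoids labelled as Trp53 floxed. If working p53 had raised them, most of 9 core targets should have risen, and otherwise only a few. The bounds set for these outcomes left a middle range undecided, and 4 rose, which lies in that range. These were Cdkn1a (2.05), Trp53inp1 (0.64), Mdm2 (0.43) and Aen (0.29). Phlda3 fell (-0.46), Ccng1 (0.04), Zmat3 (-0.14) and Sesn1 (-0.27) did not pass, Eda2r was not measured, and the median was 0.162, so this test leaves working p53 undecided. The other explanation, signalling that the inhibitor pair blocks, has only the interaction of the list beside it (camera, adjusted p = 0.000269 with an estimated correlation). That is the observation itself and not a test of the explanation, which stays open. The values per gene do not show whether Trp53 was recombined.

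The joint fall of cell cycle genes under both inhibitors was smaller than the sum of the single falls, which counts near the floor could produce. The mitosis list by itself did not pass with an estimated correlation (adjusted p = 0.135), nor did Mki67 (0.31, adjusted p = 0.611). Among the 50 of 101 members above the median level, the median interaction was 0.698 (quartiles 0.504 and 0.843), against 0.726 for the others, and their lowest level with the pair was 3.9 CPM, which argues against the floor. After the trend on GC content and effective length was removed, the median over 101 members was 0.678 (quartiles 0.472 and 0.878), against 0.721 before. The fitted trend had an SD of 0.041 over genes, small beside that median, which argues against that bias. No biological explanation was tested.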

How the results depend on the processing

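None of the alternatives given here was chosen after the result was seen. All 11 counts of genes stayed within 1.5 times their value under RLE size factors, an effective-length offset, no count filter, DESeq2, a fit to only the groups compared and a replicate block. With libraries left out in turn, the counts of the 2 interactions moved further, in 4 of the fits. The FAKi by MEKi interaction gave 707 to 1435 genes and the gemcitabine by inhibitor pair interaction 455 to 865. The lower counts come with fewer libraries, and the cause of the higher ones was not tested. Over all comparisons, 160 list calls with the preset correlation became 43 with an estimated correlation. For many lists the estimate lay above the preset 0.01, which makes camera stricter. With MEKi it was 0.47 for mitosis, 0.659 for ribosomal proteins and 0.275 for interferon response, but -0.007 for p53 targets. Calls were also lost where the estimate lay below the preset, so its size does not account for all of the change. For the triple combination against vehicle, p53 targets had an estimate of -0.009. Their adjusted p (camera) went from 0.00381 to 0.0803. Over all genes, the replicate numbers gave little sign of pairing. The 45 pairs of libraries with the same number had a median correlation of -0.004 (from -0.25 to 0.216), against -0.005 for pairs with different numbers. Of 18 libraries, 9 matched best to their own number, and no expected count was computed. In mean log2 CPM of the mitosis list, replicate 1 stood highest in every group except gemcitabine, so a shared order of replicates is not excluded. With the replicate block, 4225 genes passed for FAKi against vehicle, and the other counts kept to the same range.

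Of the genes and lists named, those that turned direction had not passed in the main analysis or in the alternative, and the cause was not tested. With each library left out in turn, the pair against MEKi ranged from -0.049 to 0.121 for Dusp6 and from -0.055 to 0.348 for Fosl1. The gemcitabine interaction ranged from -0.071 to 0.079 for Rrm1 and from -0.17 to 0.011 for Rrm2. The triple combination ranged from -0.088 to 0.131 for Ccnd1 against the pair, and from -0.132 to 0.152 for Dck against vehicle. With the effective-length offset, these were -0.059 for Ccnd1 and -0.036 for Dck. With MEKi and without a count filter, the p53 target list turned down and the acinar list up (adjusted p = 0.65 for each), and the mesenchymal list turned down with that setting (adjusted p = 0.791), with a replicate block (adjusted p = 0.972) and with fry (adjusted p = 0.825).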

Other observations

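None of the lists in this part was chosen after the result was seen. Metabolic genes moved with MEKi. In the cholesterol synthesis list, 1 of 26 measured members rose and 23 fell (1 and 23 adjusted over the list alone, adjusted p = 3.71e-08, and adjusted p = 0.198 with an estimated correlation). Pcsk9, which lowers the LDL receptor, changed by -1.40, Msmo1 by -1.37 and Sqle by -0.96. Of the hypoxia and glycolysis list, 4 of 35 measured members rose and 23 fell (4 and 24 adjusted over the list alone, adjusted p = 3.01e-07, and adjusted p = 0.0669 with an estimated correlation). The glucose transporter gene Slc2a1 (-1.56) and the lactate dehydrogenase gene Ldha (-1.15) fell, whereas Ndrg1 rose (2.43). For lysosome and autophagy genes, 22 of 47 measured members rose and 10 fell (22 and 10 adjusted over the list alone, adjusted p = 0.00984, and adjusted p = 0.33 with an estimated correlation). Cathepsin D (Ctsd) changed by 0.74 and Ctsl by -1.48. The receptor tyrosine kinase list was not called (14 of 28 measured members rose and 3 fell, with 14 and 5 adjusted over the list alone, adjusted p = 0.0603), except without a count filter (adjusted p = 0.0277) and with fry (adjusted p = 3.19e-06), although Ephb6 rose (1.55) and Epha2 fell (-1.24). The BCL2 family list was called only with fry (6 of 15 measured members rose and 5 fell, with 6 and 5 adjusted over the list alone, adjusted p = 0.625, and adjusted p = 0.00528 with fry). Mitochondrial transcripts were called higher (14 of 17 measured members rose and 0 fell, with 14 and 0 adjusted over the list alone, adjusted p = 0.00165, and adjusted p = 0.368 with an estimated correlation). Among them, mt-Nd5 changed by 0.56. The hypoxia and glycolysis list shares 2 of its 35 measured members with other lists, the BCL2 family list 3 of 15 and the receptor list 3 of 28. The p53 target list shares 8 of 33, the matrix list 6 of 35, gemcitabine handling 5 of 23, DNA replication 4 of 51 and the stress list 3 of 39. The mesenchymal list shares 5 of 29, the basal-like list 4 of 22, the YAP and TEAD list 3 of 25 and the fibroblast list 2 of 12. Calls of all these lists are therefore not fully separate results.

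In vehicle organoids the median of list members was 1.46 CPM for immune, 1.58 for fibroblast, 2.92 for endothelial, 2.74 for acinar and 0.498 for endocrine markers, against 26.5 CPM for epithelial and ductal markers. Single members stood far above these medians, such as the immune marker Cd14 (189.9 ± 3.48 CPM), the fibroblast marker Cxcl12 (97.3 ± 0.365 CPM) and the endothelial marker Flt4 (44.3 ± 2.16 CPM). Many listed members were not among the genes tested, which left 6 of 31 immune, 12 of 23 fibroblast, 9 of 20 endothelial, 5 of 31 acinar and 7 of 27 endocrine genes. The medians above cover only the members that were left. With MEKi the immune (adjusted p = 0.318), endothelial (adjusted p = 0.361), acinar (adjusted p = 0.913) and endocrine (adjusted p = 0.0895) lists were not called. With fry the immune (adjusted p = 0.000103), endothelial (adjusted p = 1.11e-07) and endocrine (adjusted p = 1.01e-06) lists were called lower. These calls rest on few members. Of the immune list 1 of 6 rose and 2 fell (1 and 2 adjusted over the list alone). Of the endothelial list 1 of 9 rose and 3 fell (0 and 3), and of the endocrine list 1 of 7 rose and 2 fell (1 and 2). Their medians were -0.016, 0.026 and -0.084. The mesenchymal list was not called (12 of 29 measured members rose and 12 fell, with 12 and 14 adjusted over the list alone, adjusted p = 0.969), and its median was below 0 (-0.12) while its mean was above it (0.18). The matrix glycoprotein gene Sparc rose (0.85) and Inhba, which encodes an activin subunit, fell (-1.78).

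Each count of genes was compared with the counts that other splits of the same 6 libraries gave. With 10 splits, of which the real one is 1, splits are too few for a share under 0.05. Each other split mixes libraries of both treatments within a group. A treatment effect then widens the spread within groups and lowers the count. The low counts of the other splits are therefore no support for the real ones. The real count and the highest other were 4345 and 1 for FAKi, 9109 and 0 for MEKi, 8874 and 0 for the pair and 4156 and 0 for gemcitabine, each against vehicle. They were 3442 and 17 for the pair against MEKi, 7722 and 0 for the pair against FAKi, 8374 and 0 for the triple combination against vehicle, 9068 and 0 for it against gemcitabine and 599 and 0 for it against the pair.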
